A study of Homo sapiens with 2 samples.

How the data were processed

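Gene expression was measured in BE(2)C cells, an established human neuroblastoma line with amplified MYCN, with the Affymetrix Human Gene 2.0 ST platform, whose probe sets lie across the exons of a transcript. Per the labels' protocols, 1 culture received an siRNA against MYCN from Qiagen and 1 received non-targeting control siRNA from Dharmacon, both with Lipofectamine 2000, and RNA was isolated 36 hours later. Per the labels' protocols, 100 ng of total RNA was labelled with the Affymetrix WT PLUS kit. Each group therefore held 1 array, and the 2 siRNAs came from different suppliers.

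The authors deposited 1 value per probe set and array. Per the submitters' processing notes, these values came from RMA, which corrects background, normalizes arrays to a common distribution and summarises the probes of a set. The RMA version, the software around it and any filter are not given in the sources used here. The deposited values were taken to be on the log2 scale, because they ran from 0.87 to 13.43 on the control array and from 1.03 to 13.38 on the MYCN siRNA array; the scale itself is not stated. The sorted values of the 2 arrays differed by at most 0.17. A change in total RNA content per cell cannot be seen after such normalization, and differences of dim probe sets are compressed. Scanner files were not used here.

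The table held 46255 probe sets. The probe-to-gene annotation used here gave 1 gene symbol for 15835 of them (34.2%) and several symbols for 0. It gave none for the other 30420, which stayed unnamed here. All 15835 identifiers matched the RefSeq gene table of GRCh38.p14, which was used for gene type and gene order only, and 0 symbols needed an update. The probe-to-gene annotation can be old or incomplete, so a missing name does not show that the platform lacks the gene. The named probe sets covered 14812 genes, of which 651 had several probe sets. No named probe set was annotated to MYCN, so the targeted gene was not analysed here, and the labels could not be checked through it. All columns of the table were matched to a sample.

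Probe sets whose mean over both arrays was at or above the median of all named probe sets (log2 value 5.99) were kept, which left 7918 probe sets of 7575 genes. Several probe sets of a gene were averaged. Over the 172 such genes, the range between probe sets of 1 gene had a median of 0.14 log2 units. Its upper decile was 0.62, and it exceeded 1 log2 unit in 3 of these genes. Each difference is the MYCN siRNA value minus the control siRNA value on the log2 scale, and folds are 2 to the power of that difference.

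With 1 array per group no replicate error exists and no test was made, so no p-value is given. Genes were counted by a fixed rule of size, at least 2-fold in either direction, with counts at 1.5-fold beside it. These counts describe the 2 arrays. The nearest available measure of spread is that of the differences themselves. Their robust standard deviation was 0.36 log2 units over the probe sets past the filter, which includes real differences and is no replicate error. The number of arrays limits the precision of every value.

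A total of 31 gene lists were fixed before the data were examined, compiled from general knowledge of neuroblastoma, MYC biology and the cell types and stress responses that such cultures could hold. Of their 949 symbols, 530 were named in the probe-to-gene annotation used here. The lists of ABC transporters and of replication-dependent histones had 0 named members and were not analysed here. For the 29 lists with at least 5 members past the filter, the median log2 difference was set against 10000 random lists of the same size, drawn with replacement within 10 bins of mean expression. A list was called low or high when at most 2.5% of the random lists had a median as low or as high. If genes differed independently of each other, 1.45 of 29 lists would be called by chance. Random lists hold unrelated genes, so they do not give the rate for co-regulated genes that move together between any 2 cultures. The interval given with a median is the central 95% of 2000 resamplings of its members, which are genes and not replicates. On simulated data with the values shuffled within bins (7575 genes, lists of 25), 4.00% of 200 unshifted lists were called. Shuffling also removes any shared movement of genes, and smaller lists were not simulated. With a shift of -0.20, 60.0% were called, and with a shift of -0.40, 99.0%. Of 200 genes shifted by 1.50 log2 units, 89.5% passed the 2-fold rule in the right direction.

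The genes named were also fixed by rule before the data were examined. They were MYCN and a list of its neighbours on the chromosome, the 12 genes with the lowest and the 12 with the highest difference past the filter (leaving out pseudogenes, small RNAs, long intergenic RNAs, olfactory receptors, keratin-associated proteins and symbols of unnamed loci or clones), and in each list up to 2 members with the most negative and 2 with the most positive difference of at least 1.5-fold, or else the 1 member with the largest difference. MYC, MAX, ODC1, SSRP1, SUPT16H, CDKN1A, NDRG1, HAND2 and GATA3 were named whatever their value, and 1 further gene fixed in this way is not reported here. Other members of a list are named as further examples, chosen after their values were seen.

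The alternatives tried were the brightest probe set of a gene in place of the average, median centring, a lowess correction of the difference over mean expression (span 0.3), quantile normalization of the 2 columns, an offset of 32 on the linear scale, no filter, a filter at the 75th percentile, the 1.5-fold threshold, and random lists not matched on expression. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.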

Results

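The comparison asked how the transcriptome of MYCN-amplified neuroblastoma cells differs after MYCN is targeted by siRNA. Genome-wide expression was measured in BE(2)C cells 36 hours after transfection, on 1 array for cells given MYCN siRNA and 1 array for cells given control siRNA. The median log2 value over 46255 probe sets was 4.94 on the control array and 4.93 on the MYCN siRNA array. Across probe sets the arrays correlated with a Pearson's r of 0.987, and across the 7575 genes past the filter with an r of 0.946; neither probe sets nor genes are independent replicates. Neither group had a replicate, so each difference below describes these 2 arrays and has no replicate error or test behind it.

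MYCN itself, the target of the siRNA, was not analysed here because no named probe set was annotated to it. MYCNOS, its antisense transcript, was not analysed either. Of the genes near MYCN on the chromosome, DDX1, an RNA helicase gene often co-amplified with MYCN, was at 10.86 on the control array and 10.56 on the MYCN siRNA array, a log2 difference of -0.30. NBAS, the next neighbour often carried on the amplicon, differed by 0.14. LPIN1 differed by -0.13, TRIB2 by 0.44 and RRM2 by 0.23, and ODC1 by -0.71. The 6 members of this list past the filter had a median difference of 0.00, with 52.8% of the random lists at or below it. MYC, the paralogue of MYCN, lay below the expression filter on average, with a log2 value of 4.66 on the control array and 5.65 on the MYCN siRNA array. MAX, the dimerization partner of MYC proteins, differed by -0.51.

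Among 7575 genes past the filter, 142 were at least 2-fold lower and 140 at least 2-fold higher on the MYCN siRNA array (1.87% and 1.85%). These counts were 88 and 70 with an offset of 32 on the linear scale, and 77 and 64 with the filter at the 75th percentile. At 1.5-fold the counts were 595 lower and 576 higher, and 6404 genes (84.5%) lay within 1.5-fold. The median difference over all genes past the filter was -0.01. Of the 12 genes with the lowest differences, HK2, which encodes 1 of the hexokinases, was at 7.95 on the control array and 5.61 on the MYCN siRNA array. The difference was -2.34, or 5.06-fold lower (probe set 16881838). POLR3G, a subunit of RNA polymerase III, was 5.04-fold lower (probe set 16987125). MT1X, a metal-binding metallothionein, was 4.10-fold lower and FJX1 was 4.01-fold lower. LTA4H, the leukotriene A4 hydrolase gene, was 3.64-fold lower, CNNM1 3.62-fold, PPTC7 3.53-fold and NT5DC3 3.36-fold. EXOSC5, a subunit of the RNA exosome, was 3.48-fold lower. The remaining members of the 12 were the ribosome assembly genes NOP16 (3.32-fold) and RRS1 (3.21-fold) and the growth factor gene FGF2 (3.25-fold).

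On the opposite side, TP53INP1, a p53-inducible gene with roles in cell death and autophagy, was at 5.63 on the control array and 8.73 on the MYCN siRNA array, a difference of 3.10 or 8.58-fold higher (probe set 17079317). It was followed by FNDC5, the precursor of irisin, at 5.01-fold higher, and by the prokineticin receptor gene PROKR1 at 4.39-fold. DBH, the enzyme that makes noradrenaline from dopamine, was at 9.51 on the control array and 11.63 on the MYCN siRNA array, a difference of 2.12 or 4.34-fold. ENTPD3, an ectonucleotidase gene, was 4.28-fold higher, SMIM18 4.21-fold, CLIP3 4.13-fold and the complement component gene C7 3.94-fold. The small GTPase gene RRAS was 3.85-fold higher, GPR137C 3.62-fold, the polo-like kinase gene PLK2 3.44-fold and the signalling adaptor gene GAB2 3.33-fold. The value on 1 of the arrays lay below the filter level of 5.99 for TP53INP1, PROKR1, ENTPD3, SMIM18, PLK2 and GAB2 among these genes, and for HK2, POLR3G, CNNM1 and NT5DC3 among the lowest. That value was not shown to be above background, so the folds and ranks of these genes are less certain than those of genes bright on both arrays. The same limit holds for genes named further on with 1 value under that level. RPL22L1, PRMT1, XIAP, IRF9 and IFI35 are among them.

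**Figure D1:**
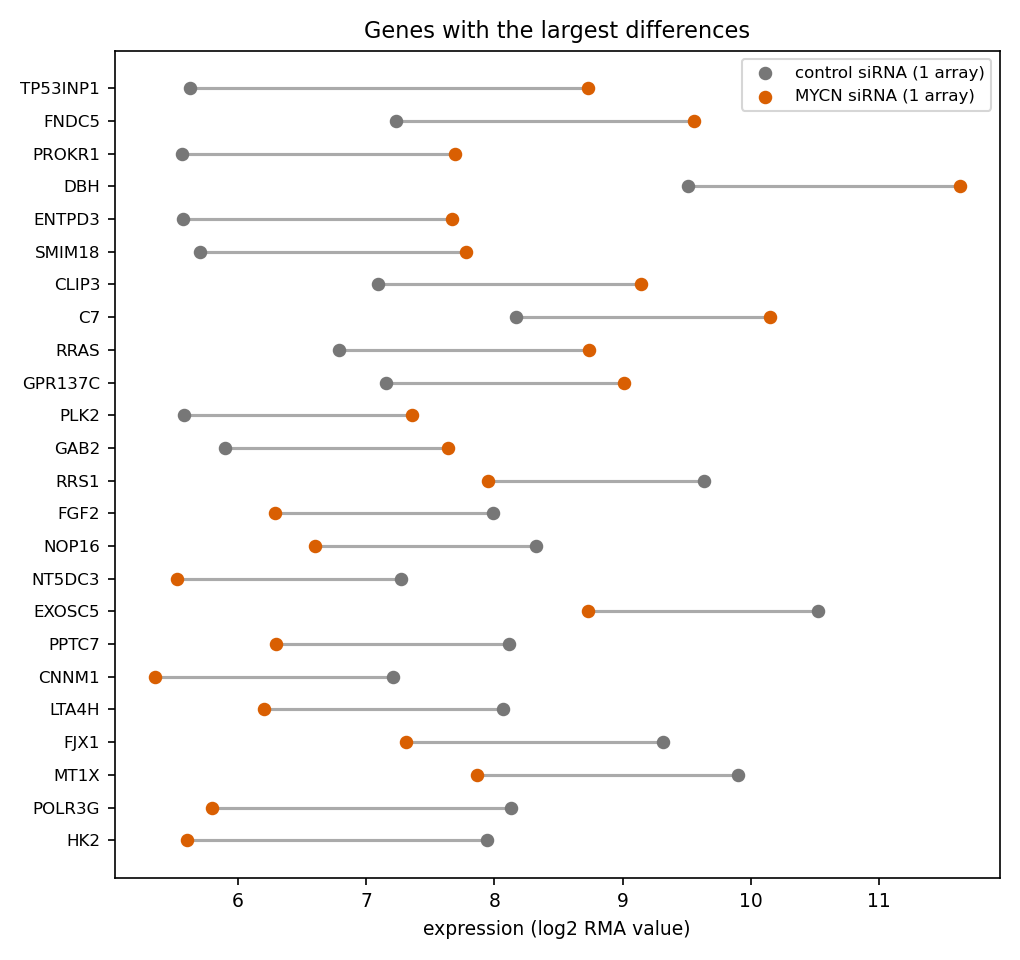
Log2 RMA value (x axis) of the 12 genes with the lowest and the 12 with the highest difference past the filter, with 1 point for the control siRNA array (grey) and 1 for the MYCN siRNA array (orange), joined by a line. TP53INP1 spans 5.63 to 8.73 and HK2 spans 7.95 down to 5.61; no replicates exist, so no error bars are drawn.

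Genes of ribosome assembly and rRNA processing were lower on the MYCN siRNA array as a group. All 38 members past the filter had a negative difference, 33 were at least 1.5-fold lower and 17 at least 2-fold lower, and 0 were higher. The median difference was -0.93 (central 95% of resampled members -1.17 to -0.72), and 0 of 10000 random lists matched on expression had a median as low. NOP16, a nucleolar protein gene, differed by -1.73, and RRS1, which acts in assembly of the large ribosomal subunit, by -1.68. Other members included the rRNA dimethylase gene DIMT1 at -1.55, the RNA helicase gene DDX21 at -1.17, NCL (nucleolin) at -0.69 and FBL (fibrillarin) at -0.64. The smallest difference in the list was that of NOP10, at -0.14.

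The listed genes for structural proteins of the cytosolic ribosome were lower by smaller amounts. All 30 members of the list past the filter had a negative difference, with a median of -0.42 (-0.54 to -0.33), and 9 were at least 1.5-fold lower; 0 of 10000 random lists were as low. RPL22L1, a paralogue of RPL22, differed by -1.45 and RPL11 by -0.80, while RPL8 differed by -0.12. Over all symbols with the stem RPL or RPS past the filter, which can include related genes and pseudogenes, 5 of 40 and 3 of 20 had a positive difference (medians -0.33 and -0.35). Ribosomal protein genes have many processed pseudogenes, and array probes cannot always separate these from the parent gene. Of the 25 listed genes of the mitochondrial ribosome and protein import, all had a negative difference and 10 were at least 1.5-fold lower, with a median of -0.41 (-0.61 to -0.31) and 0 of 10000 random lists as low. TIMM13, an import chaperone gene, differed by -0.98 and MRPL3 by -0.86. The unanimous sign held for the listed genes and not for all genes with such symbols, a count made after the values were seen. Of 48 MRPL symbols past the filter 8 had a positive difference (median -0.21), of 25 MRPS symbols 2 (median -0.28) and of 13 TIMM symbols 2 (median -0.41).

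Other parts of the protein synthesis machinery were also on the lower side. Of 17 aminoacyl-tRNA synthetase genes, 15 had a negative difference (14 after lowess correction or quantile normalization) and 5 were at least 1.5-fold lower, with LARS1 at -0.81 and YARS1 at -0.68; the median was -0.42 and 0 of 10000 random lists were as low. Of the 24 symbols in the translation list, 8 were named, and 3 of these 8 genes were at least 1.5-fold lower. These were the factors EIF5B at -1.35 and EIF5A at -0.94, and EIF4EBP1 at -0.88, which encodes an inhibitor of translation initiation. The median of all 8 was -0.39, with 0.56% of random lists as low. This call was lost with the brightest probe set per gene (261 of 10000 as low) and with the filter at the 75th percentile (402 of 10000). Among all symbols past the filter with the stems EIF and EEF, 5 of 21 and 4 of 9 had a positive difference (medians -0.21 and -0.11). Chaperone genes had a median of -0.48, with 7 of 8 negative, 3 at least 1.5-fold lower and 0.10% of random lists as low; TRAP1, a mitochondrial chaperone gene, differed by -0.91 and HSPH1 by -0.88.

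Of the metabolic lists, nucleotide synthesis and serine, one-carbon and glutamine metabolism were called low, and polyamine metabolism, glycolysis and hypoxia were not called. Of 17 genes of nucleotide synthesis, 9 were at least 1.5-fold lower and 0 higher, with a median of -0.59 (-0.82 to -0.25) and 0 of 10000 random lists as low. PFAS, an enzyme of de novo purine synthesis, differed by -1.24 and IMPDH2, which commits inosine monophosphate to guanine nucleotides, by -0.94, while RRM2 differed by 0.23. Of 7 genes of serine, one-carbon and glutamine metabolism, 5 were at least 1.5-fold lower, with a median of -0.79 (-1.29 to -0.49) and 0 of 10000 random lists as low. MTHFD1L, a mitochondrial folate enzyme gene, differed by -1.32 and PSAT1, of serine synthesis, by -1.29. The other 5 were PHGDH, SHMT2, SHMT1, PSPH and the asparagine synthetase gene ASNS. Only 8 of the 19 symbols of this list were named. No glutaminase or glutamine transporter gene was among the 7, so the call describes serine and one-carbon genes and not glutamine metabolism. In the polyamine list the median was 0.01, with 57.0% of random lists at or below it. Its 3 members at least 1.5-fold lower were the synthesis genes SRM at -0.98, ODC1 at -0.71 and AMD1 at -0.63. The glycolysis list, of which 9 of 22 symbols were named, had a median of -0.10 (26.9% of random lists as low). HK2 was the 1 of these 9 that reached 1.5-fold. HK1, which encodes another hexokinase, differed by 0.01, LDHA by 0.10 and GAPDH by 0.21. The hypoxia list had a median of 0.06 (65.3% as low), again with HK2 alone at 1.5-fold; without the filter its median was -0.07.

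Both cell cycle lists were called low, with small differences in most members. Of 30 genes of G1/S and DNA replication, 29 had a negative difference, 4 were at least 1.5-fold lower and 0 higher, with a median of -0.32 (-0.41 to -0.23) and 1 of 10000 random lists as low. Cyclin E1 (CCNE1) and the phosphatase gene CDC25A each differed by -0.76, and cyclin D1 (CCND1) by 0.41. Of 31 mitotic genes, 27 had a negative difference (25 after lowess correction), some of them close to 0 such as KIF11 at -0.02, and 4 were at least 1.5-fold lower, with a median of -0.29 (-0.40 to -0.14) and 5 of 10000 random lists as low. CDC20, an activator of the anaphase-promoting complex, differed by -0.66 and AURKA, the Aurora A kinase gene, by -0.65, whereas the proliferation marker MKI67 differed by 0.11.

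The list of chromatin regulators was called low and that of the MYC network was not. In the list of FACT and chromatin regulators, 19 of 21 members had a negative difference, 5 were at least 1.5-fold lower and 0 higher, with a median of -0.26 (-0.39 to -0.21) and 0.51% of random lists as low; with the filter at the 75th percentile the median was -0.39. The arginine methyltransferase genes PRMT1 and PRMT5 differed by -0.96 and -0.92. Of the 2 subunits of FACT, a histone chaperone, SSRP1 differed by -0.70 and SUPT16H by -0.26. The MYC network list had a median of -0.19 and 3 of 16 members at least 1.5-fold lower, RUVBL1 at -0.91, RUVBL2 at -0.72 and AURKA. It was not called, with 4.34% of random lists as low, but passed with the brightest probe set per gene (232 of 10000).

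**Figure D2:**
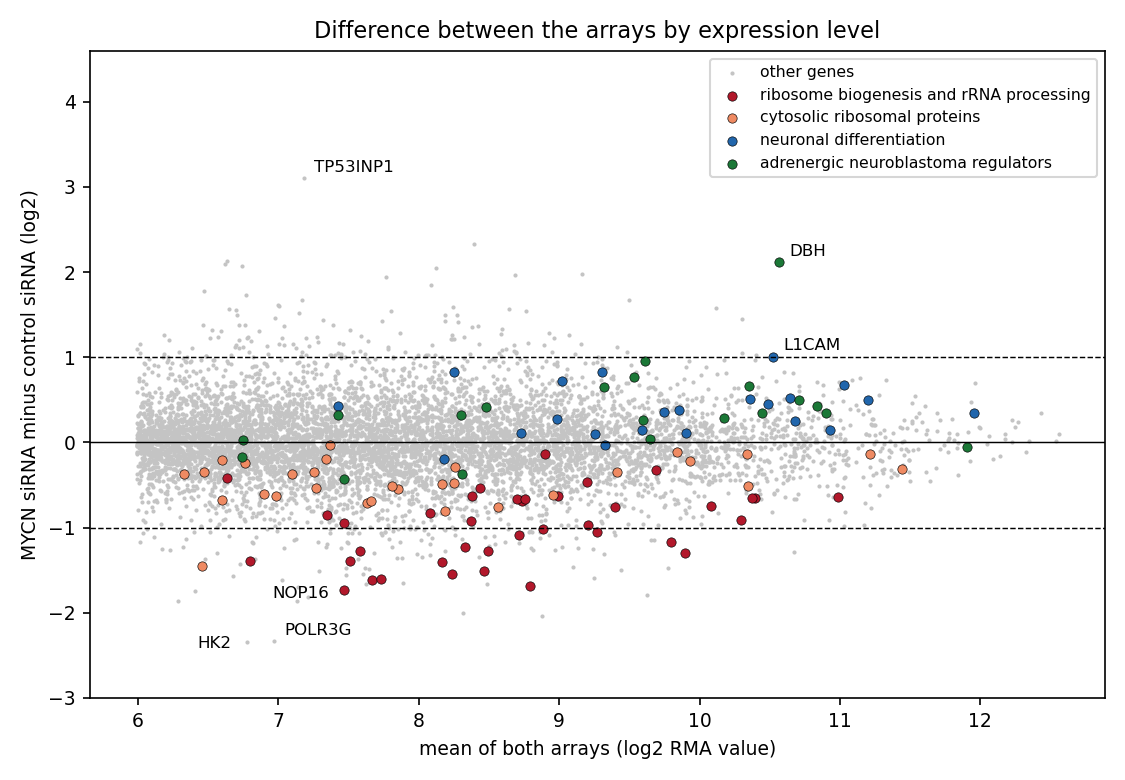
Difference between the arrays (y axis, MYCN siRNA minus control siRNA, log2) against the mean of both arrays (x axis, log2 RMA value) for the 7575 genes past the filter, 1 point per gene, with 4 of the fixed lists coloured and dashed lines at 2-fold. All 38 ribosome biogenesis genes (red) lie below 0, and 20 of 22 neuronal differentiation genes (blue) lie above it.

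Neuronal and noradrenergic genes were on the higher side. Of 22 neuronal differentiation genes, 20 had a positive difference, 5 were at least 1.5-fold higher and 0 lower, with a median of 0.37 (0.20 to 0.51) and 0 of 10000 random lists as high. L1CAM, a neural cell adhesion gene, differed by 1.01, the synaptic vesicle gene SYN1 by 0.83 and NCAM1 by 0.83, while GAP43, a growth cone gene, differed by 0.11 and MAPT by -0.20. Of 20 adrenergic neuroblastoma genes, 16 had a positive difference and 5 were at least 1.5-fold higher, with a median of 0.33 (0.16 to 0.46) and 0 of 10000 random lists as high. Beside DBH, the receptor tyrosine kinase gene RET differed by 0.96, PHOX2A by 0.77, HAND2 by 0.42 and GATA3 by 0.29. TH, the first enzyme of catecholamine synthesis, differed by 0.03 and INSM1 by -0.44.

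Markers of mesenchymal and Schwann-type cells, included because other cell states could be present in such a culture, had 9 of 22 named members past the filter. S100B differed by 0.82 and TWIST1 by 0.66, both at least 1.5-fold higher, while SNAI2 differed by -0.51. The median was 0.28 (-0.34 to 0.66), with 2.45% of random lists as high. It was lost without the filter, where the median was 0.08 and 800 of 10000 random lists were as high, and in 3 further settings that lay close to the limit.

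Genes listed beforehand as repressed by MYCN were higher on the MYCN siRNA array. All 11 members past the filter had a positive difference and 4 were at least 1.5-fold higher, with a median of 0.45 (0.28 to 1.0) and 0.08% of random lists as high; 3 more named members lay below the filter. DKK3, a secreted protein gene of the Dickkopf family, differed by 1.11, the transcription factor gene EGR1 by 1.10, and NDRG1 by 0.07. Immediate early genes, which respond quickly to growth factors and stress, had 16 of 22 members positive and 7 at least 1.5-fold higher, with a median of 0.41 (0.08 to 0.60) and 0 of 10000 random lists as high. KLF2 differed by 1.19 and DUSP6, a phosphatase gene that acts on ERK, by 1.03, while FOS differed by 0.14. Without the filter the median of this list was 0.20.

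The list of CDK inhibitors and p53 targets held the gene with the highest difference and was not called as a group. Its median was -0.15, with 11.5% of random lists as low, and 3 of 13 members were at least 1.5-fold higher and 1 lower. The sign of this median depended on the filter: it was 0.03 without one and -0.38 at the 75th percentile (526 of 10000 as low). TP53INP1 differed by 3.10, PLK2 by 1.78 and TP53I3 by 1.36, whereas PMAIP1, which encodes the pro-apoptotic protein NOXA, differed by -0.62, BAX by -0.38 and RRM2B by 0.22. CDKN1A was not analysed here. Of 11 apoptosis regulators, 10 had a positive difference, with a median of 0.36 (0.22 to 0.66) and 0.54% of random lists as high. The members at least 1.5-fold higher were XIAP at 0.95 and BCL2 at 0.78, which inhibit cell death, and APAF1 at 0.66, which promotes it. BID, a pro-apoptotic BH3 gene, differed by -1.15. This call was lost with the filter at the 75th percentile (768 of 10000 as high).

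Lysosome and autophagy genes had 13 of 16 positive differences and a median of 0.26 (0.15 to 0.34), with 0.68% of random lists as high; LAMP2, a lysosomal membrane gene, was the 1 member that reached 1.5-fold, at 0.61. The call was lost with the filter at the 75th percentile (284 of 10000). The interferon, unfolded protein, cholesterol, small RNA machinery and reference lists lay in the middle of the random lists. The interferon list had a median of -0.06 over 9 members past the filter (34.5% as low), and 22 of its 31 named members lay below the filter; IRF9 differed by 1.01, IFI35 by 0.94 and USP18 by -0.66. The ATF4 and unfolded protein list had a median of 0.03 (62.9% as low), with ATF3 at 0.73. The cholesterol list had a median of -0.07 (28.0% as low), with DHCR7 at -0.70 and TM7SF2 at 0.67. The small RNA machinery list had a median of -0.09 (35.0% as low), with XPO5 at -0.71 and TNRC6B at 0.86. Reference genes had a median of 0.01 (55.8% as low), and HPRT1, at -0.60, was the 1 of 13 that reached 1.5-fold.

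**Figure D3:**
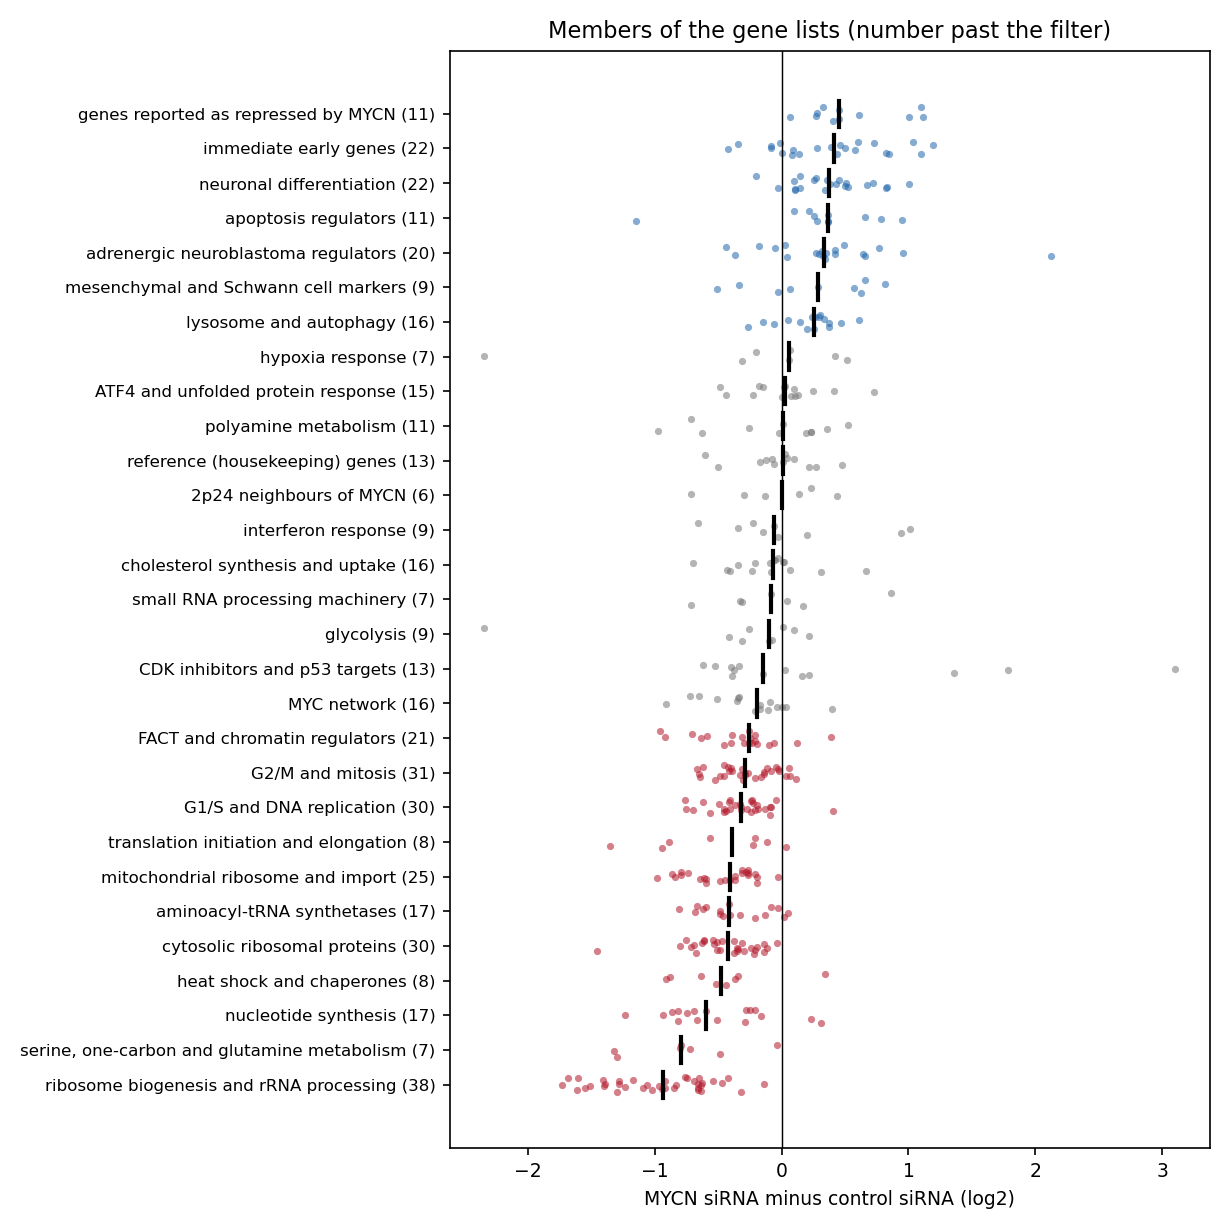
Log2 difference (x axis, MYCN siRNA minus control siRNA) of every member past the filter in each of the 29 gene lists (y axis, number of members in brackets), 1 point per gene with vertical jitter for display and a black bar at the median. Red lists were called low (11), blue lists high (7) and grey lists neither (11), against 10000 random lists matched on expression; the ribosome biogenesis list has the lowest median, at -0.93.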

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

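The counts in this part were made after the main differences had been seen. The 30420 unnamed probe sets entered no comparison of genes or lists, and they also held signal. Among the 7086 of them past the same expression filter, 136 were at least 2-fold higher on the MYCN siRNA array than on the control array and 155 were at least 2-fold lower, with differences from -2.28 to 2.59.

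MicroRNA genes were part of the gene counts, but the rule for named genes left them out; 1123 named probe sets were annotated to them. Of the 166 past the filter, 5 were at least 2-fold higher on the MYCN siRNA array and 0 at least 2-fold lower, with no test possible. MIR637 drew attention with a difference of 1.97, from 7.70 to 9.67, and the other 4 were MIR218-2 at 1.32, MIR329-1 at 1.16, MIR21 at 1.16 and MIR548H2 at 1.11. The signal of such probe sets can include the longer host transcript.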

How the results depend on the processing

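No paired analysis was possible because each group held 1 array, and for the same reason no replicate could be left out. The alternatives for the MYCN level were not run, since it had no named probe set. The counts of genes at least 2-fold lower and higher (142 and 140) were 88 and 70 with an offset of 32 on the linear scale, which shrinks differences by construction, 77 and 64 with the filter at the 75th percentile, which tests fewer genes, and 595 and 576 at 1.5-fold. Under the other 5 settings they ranged from 131 to 159 and from 142 to 179. Of the 282 genes, 268 were shared with the calls under quantile normalization, 275 under lowess correction and 156 under the offset. All 227 alternative values of the 29 list medians lay inside the resampled interval of the reported median. This is a loose criterion, since the interval reflects the spread of the members. The immediate early median fell from 0.41 to 0.20 without the filter and still lay inside. Random lists not matched on expression leave the median itself unchanged by construction. The ribosome biogenesis median ranged from -0.95 to -0.83, the neuronal median from 0.35 to 0.41 and the adrenergic median from 0.31 to 0.39. Of 18 called lists, 14 kept their call under every alternative that gave a value. The filter at the 75th percentile left too few members for a median in the serine, glycolysis, hypoxia, interferon and mesenchymal lists. Among lists that were not called, the median changed sign without the filter in the p53, hypoxia and interferon lists and at the 75th percentile in the polyamine list (-0.02). The exceptions were the translation, apoptosis, lysosome and mesenchymal lists. The mesenchymal call was lost in 4 settings, among them lowess correction (274 of 10000 as high) and random lists not matched on expression (255 of 10000), against 245 in the reported setting and a limit of 2.5%. The cause of these changes of call was not tested. Signal over background was not given for single probe sets, so the filter stands in for detection.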

Other observations

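The tests of growth, innate response, copy number and paralogues were chosen after the differences they concern had been seen, as were the gene families named here; the tests of intensity bias, zinc supply and glucocorticoid response were fixed before their results. Families were formed from shared symbol stems, 235 of them with at least 5 members past the filter, and set against 10000 random lists. At a limit of 25 random lists, 15 families were low and 4 high. If genes differed independently of each other, 0.59 on each side would be reached by chance. Many of the low ones, such as RRP, NOP, RPL, RPS, MRPL, TIMM and PRMT, share members with fixed lists called low. They are therefore not separate findings. The low ones also included several RNA-handling families outside the fixed lists. All 10 RNA exosome genes had a negative difference (median -0.52), among them EXOSC5 at -1.80 and EXOSC6 at -0.07. With its 2 probe sets averaged whatever their level, EXOSC10 differed by -0.02. Within the low POLR family, all 4 RNA polymerase III genes past the filter were lower, with POLR3G at -2.33, POLR3E at -1.10 and POLR3B at -1.02, while POLR3GL, the paralogue of POLR3G, lay below the filter, at 5.34 on the control array and 5.83 on the MYCN siRNA array. The small nucleolar RNA host genes had 6 of 8 negative differences (median -0.50), from SNHG8 at -1.17 to SNHG20 at 0.45. The NUP family had 17 of 19 negative differences (median -0.33); its highest member, NUP50-DT at 0.59, is a long non-coding RNA. Without that RNA, 17 of 18 differences were negative (median -0.34). The medians of these groups, with the NUP family taken without that RNA, stayed negative after median centring, lowess correction, quantile normalization and the offset of 32. This is weak support, because an offset cannot change the sign of a probe set's difference. The other steps moved the medians little, as for RNA polymerase III from -1.06 to -1.03 under quantile normalization.

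The 4 high families were the protocadherin beta genes, the Krüppel-like factors, the ZNF zinc finger genes (292 members, median 0.10) and the symbols with the stem TP (9 members, median 0.45), most of which name p53-related genes, TP53INP1 among them. The TP family passed narrowly, with 24 of 10000 random lists as high. Plexins, the receptors of semaphorins, were formed as a separate group and are not among the 235 families. They had 7 of 8 positive differences (median 0.45; 8 of 8 after lowess correction or quantile normalization, where PLXNA1 changed sign), with PLXNA2 at 1.67 and PLXNB3 at 1.38. Krüppel-like factor genes had 8 of 11 positive differences (median 0.43), and 8 of 10000 random lists were as high, though KLF2, KLF6, KLF7 and KLF10 are also in the fixed lists. In the table as a whole, 2086 probe sets (4.51%) had exactly equal values on both arrays, while 41 differed by at most 0.001. The equal probe sets had a median level of 3.59 against 5.02 for the rest.

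The lower level of the ribosome biogenesis list was weighed against technical explanations. An intensity-dependent bias left in the normalized values is argued against. Over all probe sets, the median difference in each of 10 bins of mean expression lay between -0.04 and 0.002. The lowess correction could therefore move the list only a little, and the list's median stayed at -0.92 after it. An innate response to the siRNA stays open: the 31 named members of the interferon list had a median of 0.0033 (central 95% of resampled medians -0.15 to 0.20), but 22 lay below the filter and members went both ways. Slower growth of 1 culture stays open, because the higher of the medians of both cell cycle lists was also below 0, at -0.29, and 1 culture per siRNA confounds growth with the siRNA. Loss of MYCN, an off-target effect of a single siRNA and chance variation between cultures may each contribute. So may the different suppliers of the MYCN and control siRNAs. The design cannot separate these, and the MYCN level itself was not analysed here.

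The clustered protocadherin beta genes, which encode neuronal cell surface proteins, had the highest median of the 235 families. All 14 members past the filter, 2 transcribed pseudogenes among them, were higher on the MYCN siRNA array, 12 by at least 1.5-fold, with a median of 1.004, from PCDHB3 at 0.56 to PCDHB15 at 1.67; 0 of 10000 random lists were as high. The 5 members below the filter differed by -0.13 (PCDHB1), -0.06 (PCDHB17P), 0.67 (PCDHB5), 0.84 (PCDHB11) and 1.49 (PCDHB8). A change in copy number of a segment that reaches the flanking genes is argued against. The 10 nearest genes past the filter, with all protocadherin genes left out, had a median of -0.19 (SD 0.23). A change limited to the protocadherin genes would not be seen in this way. Signal shared between similar paralogues stays open: the members' differences had an SD of 0.36, and the robust SD of all named probe sets past the filter was also 0.36, and probe sequences were not used here. A shared change in regulation of the cluster is a hypothesis that may account for the pattern and was not tested.

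Metallothionein genes, which bind zinc and copper, were lower among the members past the filter, too few for a comparison with random lists. MT1X differed by -2.04, MT2A by -1.66 and MT1F by -0.54, the 3 members past the filter. The 6 members below it differed by -1.55 (MT1G), -0.54 (MT1E), -0.37 (MT1L), -0.24 (MT1H), -0.18 (MT1M) and 0.34 (MT1B). A test of zinc supply through the exporter gene SLC30A1 could not be made, since it had 0 named probe sets. A weaker glucocorticoid signal, which also drives these genes, could not be decided: 6 responsive genes had a median of -0.27 (central 95% of resampled medians -0.56 to 0.78), with PER1 at -0.66 and SGK1 at 0.92. A difference in medium between the cultures and an effect of the MYCN siRNA may both give this pattern, and they cannot be told apart with 1 array each.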
